A study of Mus musculus with 18 samples.

How the data were processed

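RNA was measured in 18 polyA-selected libraries of mouse SGET cells, 3 for each of 6 groups: WT and Esrrb KO cells as EpiLC, as PGCLC at day 3 and as PGCLC at day 5. EpiLC were unsorted, and PGCLC were sorted for the Stella reporter and low Esg1 reporter signal. Groups were taken from the labels. The late libraries are called day 6 in some descriptions and 5 days of culture in others, and are called day 5 here. A KO line is named A2 in descriptions and KO2 in titles, and is called A2 here. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.3.1, and the genome is named as mm10 and as GRCm38.p4. The aligner, the counting tool, its annotation and its strand setting are not given in the sources used here, so counts of genes that overlap on opposite strands (Xist and Tsix, Nespas and Gnas, Airn and Igf2r) or have near-identical copies (2-cell-like, Ifitm, Rhox, Oas and Gbp families) are uncertain.

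The deposited values are raw counts per Ensembl gene for each library and, for the whole series, deposited CPM. In all 18 columns the CPM values equal the counts divided by the library total to within 1e-06. Each count file lists 25965 rows, of which 56 carry no gene ID and were left out (0.0559% to 0.0828% of the counts of a library), leaving 25909 genes. Library totals ran from 3032965 to 5286330 counts. A group at 0 counts was set against a floor of 3 counts over the group, and with 1 to 3 counts a ratio is given with its exact binomial 95% counting interval. Symbols came from the deposited table and positions from GENCODE M21 (GRCm38), which need not be the annotation the authors used.

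Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (12856) were scaled by TMM (factors 0.964 to 1.04) and fitted in a single model with a mean for each of the 6 groups by robust quasi-likelihood (common dispersion 0.0283, median prior degrees of freedom 4.37). Calls used a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The 9 comparisons were KO against WT at each of 3 stages, day 3 against EpiLC and day 5 against day 3 in each genotype, and the interaction of KO with each step. Agreement between stages counts genes called in the same direction at 2 or more stages. Principal components used log2 CPM with a prior count of 2. All 29 gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, whose test in 1 direction asks whether the genes of a list move on balance the same way and whose mixed test asks whether they change in either direction. Neither fry test compares a list with other genes. Adjusted p of lists are over the 29 lists of a comparison, or over 30 for the interferon-stimulated list, which was added to them. Called lists in the order of the 9 comparisons numbered 15, 8, 7, 12, 2, 10, 14, 9 and 6 with camera, and 9, 6, 6, 18, 0, 14, 2, 6 and 0 with fry in 1 direction.

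Genes named in the text follow a rule fixed with the design: Esrrb, the 8 highest and 8 lowest log2 fold changes of each KO comparison, 6 and 6 of each step and 5 and 5 of each interaction, among called genes with at least 5 CPM in the higher group and, for 2 groups, no overlap between libraries, with predicted gene models passed over. Up to 4 members of each list with the largest changes and a fixed set of pluripotency, germ cell and germ layer genes may also be named. Ddx3y, Eif2s3y, Fn1 and the genes given for single EpiLC libraries were chosen after their values were seen, unless they belong to this set. Some genes open to naming by this rule are not reported here.

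The pipeline was tested on simulated data with 12711 tested genes and 200 changed genes. In the simulated KO effect at day 3 edgeR recovered 28.4%, 71.6% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold, and called 0.08% of unchanged genes. For the simulated interaction it recovered 4.5%, 50.7% and 78.8%. The simulation gave WT and KO the same spread and held no effects of KO lines or chromosomes, so these shares need not hold for the real libraries. Changed genes were drawn only above a minimum mean CPM, so the shares do not cover genes near 0 counts. A simulated list of 20 raised genes was called by camera, but simulated genes vary independently, so this does not cover lists whose genes move together.

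Alternatives planned with the design were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma-trend on log2 of the deposited CPM plus 1, a fit of only the groups compared, leaving out each library, a block for replicate names and, for agreement between stages, an absolute log2 fold change of at least 1. Whether names pair libraries was checked by correlating the deviations from the group mean. By this check KO line names paired them (9 of 9 pairs above 0.1, 0.11 to 0.588), while WT numbers did not (-0.048 to 0.066). On chromosome 8, though, the median log2 ratio of genes to the WT mean went with the WT number at every stage. It was 0.02 to 0.051 in WT 2 and -0.04 to -0.013 in WT 3. WT numbers thus mark some shared difference that the correlations did not show. Chosen after seeing the data were leaving out all libraries of line A2, limma-voom with a variance per group, and leaving out genes on chromosomes 1, 8, 11, 16 and Y. For single genes this last setting kept the main fit and repeated only the adjustment of p over the remaining genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.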

Results

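Polyadenylated RNA was sequenced from mouse cells at 3 stages of a route from embryonic stem cells to germ cells in culture, in WT cells and in cells labelled Esrrb KO. The starting SGET line carries reporters linked to Stella (Dppa3) and Esg1 (Dppa5a). Epiblast-like cells (EpiLC, made with activin A and bFGF, unsorted) were followed by primordial germ cell-like cells (PGCLC, made with BMP4, LIF, SCF, BMP8a and EGF) sorted by both reporters after 3 or 5 days. Each of the 6 groups held 3 libraries, 18 in all, with 3032965 to 5286330 counts per library (median 4246221). The WT replicates carry numbers and the KO replicates the names A5, B1 and A2, and nothing in the labels says whether the WT replicates were separate cultures. Counts of WT pairs in a group differed by little more than counting noise (chi-square per degree of freedom 1.135 to 1.875), against 4.118 to 36.025 for KO pairs. The spread among WT libraries may thus be largely technical. Chromosome 8 is an exception, as differences between WT libraries there went with the replicate number at all 3 stages. The p-values use a single spread per gene estimated over all 18 libraries, KO lines included, so for WT they do not measure the WT spread alone. Levels are mean CPM (counts scaled to the TMM-adjusted library total) ± SD of 3 libraries, and log2 fold changes are given ± SE with Benjamini-Hochberg adjusted p from edgeR over 12856 tested genes (n = 3 against 3). Dppa3 and Dppa5a drive the sort gate, so no change between unsorted and sorted cells is read from them. Gene lists, comparisons, the rule for naming genes and most alternative settings were fixed before the data were examined. Of the calls of gene lists by camera given here, only that of the neural ectoderm list between EpiLC and day 3 in KO also passed with an estimated correlation. Floors and counting intervals given for genes near 0 counts cover counting error only.

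Esrrb (ENSMUSG00000021255, chromosome 12, 86361117 to 86521628, GRCm38), an orphan nuclear receptor of naive pluripotent cells, was the gene named as knocked out. In WT EpiLC the 3 libraries held 127, 113 and 79 Esrrb counts. KO EpiLC held 29 counts in A5 and 18 in B1, while the library labelled KO A2 held 167, above every WT EpiLC library and against its label. At day 3, WT libraries held 2596, 3125 and 2691 counts, and KO libraries 745 (A5), 499 (B1) and 359 (A2). At day 5, WT libraries held 2930, 2987 and 2434 counts, and KO libraries 600 (A5), 933 (B1) and 631 (A2). Esrrb was lower in KO at day 3 (log2 fold change -2.13 ± 0.43, adjusted p = 0.00554) and day 5 (-1.89 ± 0.42, adjusted p = 0.00598), and did not pass in EpiLC (-0.68 ± 0.52, adjusted p = 0.401). The deleted part of the gene is not given, so counts over the whole gene need not show a deletion, and transcript remained in every KO library. The plot of Esrrb shows the values per library.

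**Figure D1:**
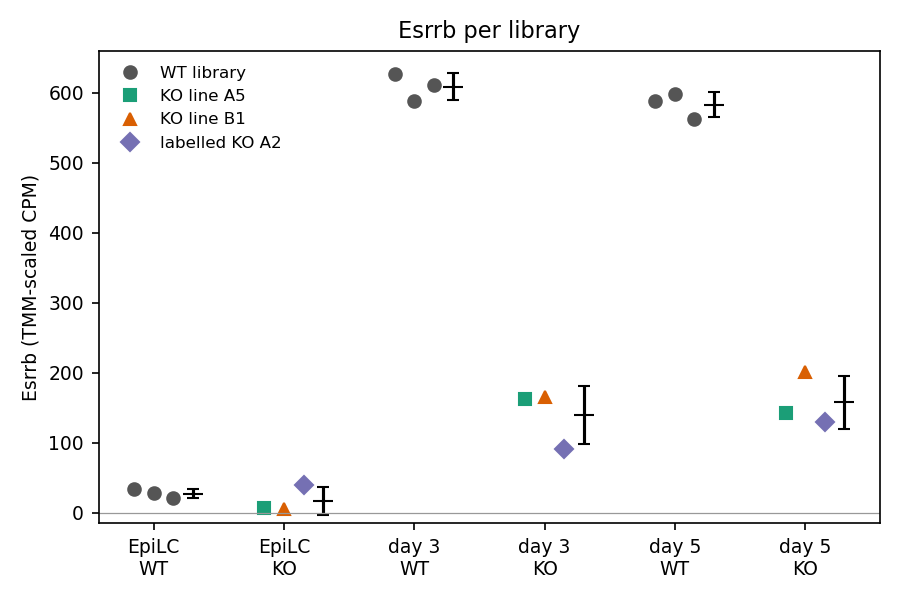
Esrrb in TMM-scaled CPM for each of the 18 libraries, by stage and genotype, with the mean and SD of each group. The EpiLC library labelled KO A2 (39.8 CPM) lies above the WT EpiLC libraries, and every KO PGCLC library lies below every WT PGCLC library.

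Across all genes the first principal component held 56.45% of the variance and the second 14.7%. WT libraries of a stage lay close together, while all 3 libraries of line A2 lay apart on the second component (-62.1 in EpiLC, -42.16 at day 3 and -42.48 at day 5, against at least -23.17 elsewhere). On the third (8.18% of the variance) the EpiLC library labelled KO A2 stood alone (-63.83, against at least -18.41 elsewhere). In that library Otx2 and Dnmt3b, genes of formative epiblast, were at 14.5 and 701 CPM, against 103 to 119 and 2920 to 2961 CPM in WT EpiLC. Nanog and Tfcp2l1, genes of naive pluripotency, were at 63.8 and 74.3 CPM there, against at most 32.0 and 15.7 CPM in WT EpiLC. The matrix gene Fn1 (5474 CPM) and the keratin gene Krt8 (487 CPM) were also higher there than in any other EpiLC library, where they reached at most 436 and 68.8 CPM. Pou5f1, at 671 CPM, lay between the other KO EpiLC libraries (532 and 601 CPM) and the WT EpiLC libraries (777 to 836 CPM).

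**Figure D2:**
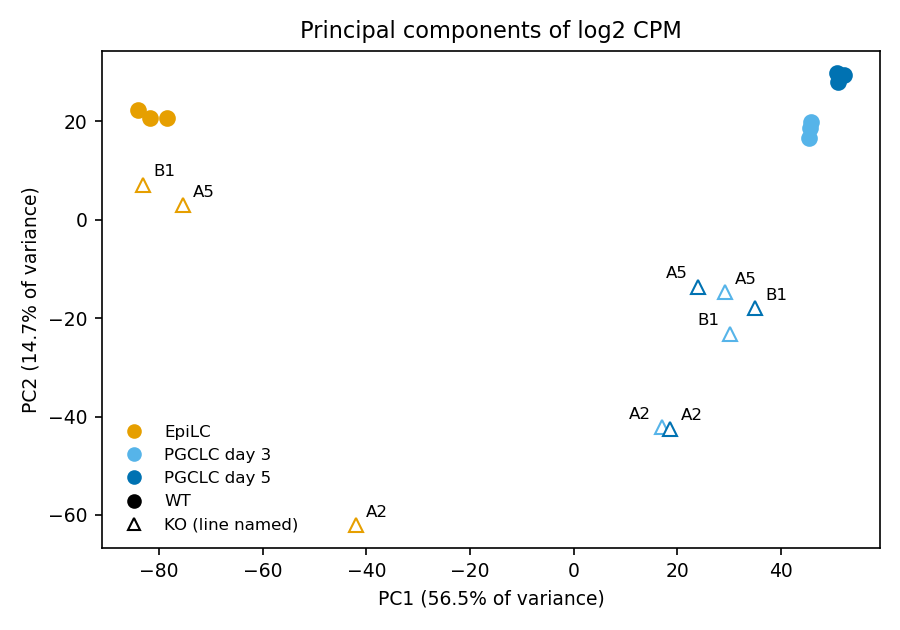
First and second principal components of log2 CPM for the 18 libraries, coloured by stage, with filled circles for WT and open triangles for KO libraries. The EpiLC library labelled KO A2 lies apart from the other EpiLC libraries.

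KO and WT EpiLC were compared to ask which genes depend on Esrrb before germ cell induction. Of formative epiblast and glycolysis genes 4 of 23 and 9 of 29 were called lower in KO EpiLC, and of p53 targets 8 of 21 higher. With an estimated correlation 0 of these lists were called. Fgf5, a growth factor of formative epiblast, fell (-1.40 ± 0.35, adjusted p = 0.0235), as did the epiblast transcription factor Otx2 (-1.36 ± 0.38, adjusted p = 0.0337) and the DNA methyltransferase gene Dnmt3a (-0.69 ± 0.15, adjusted p = 0.0144). The glycolytic enzyme genes Ldha and Eno1 fell by smaller amounts (-0.68 ± 0.13 and -0.66 ± 0.09). Cdkn1a, a p53 target that slows the cell cycle, rose (147 ± 79.3 against 47.8 ± 2.87 CPM, log2 fold change 1.62 ± 0.25, adjusted p = 0.00395). Krt8 (4.61 ± 0.84) and Col1a1, a fibrillar collagen (4.70 ± 0.81), rose as well. Fgf5, Otx2 and Dnmt3a missed the threshold without WT 1, WT 2 or WT 3 (adjusted p up to 0.105). Without the library labelled KO A2 the log2 fold changes were 2.62 for Krt8 and 3.64 for Col1a1.

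Among the genes that rose most in KO EpiLC were Wisp1 (ratio 457, 95% counting interval 81.7 to 18100), Tgfbr2 (ratio 88.1, 95% counting interval 29.8 to 430.0), Wnt7b, Gata2 (ratio 94.6, 95% counting interval 16.6 to 3770), Csf1, Tinagl1 and Tgm2. Among those that fell most were Rcsd1, Xist, Ccdc3, Rhox5, Dcn, Slc35d3 and Aire, from -1.97 ± 0.59 for Rcsd1 to -1.64 ± 0.43 for Aire. Wnt7b, a WNT ligand, held 5 counts in WT and 420 in KO EpiLC. Wisp1, Wnt7b, Tgm2, Xist, Rhox5 and Slc35d3 missed the threshold without WT 1, WT 2 or WT 3 (adjusted p up to 0.102). Tgfbr2 missed the threshold without WT 1 or WT 2 (adjusted p up to 0.0541). Gata2 and Tinagl1 missed the threshold without WT 1, WT 2, WT 3 or the library labelled KO A2 (adjusted p up to 0.0786). Rcsd1 missed the threshold without WT 1, WT 2, WT 3 or KO B1 (adjusted p up to 0.112). Aire missed the threshold without WT 1, WT 2, WT 3, KO B1 or the library labelled KO A2 (adjusted p up to 0.099). Csf1 missed the threshold without WT 2 or WT 3 (adjusted p up to 0.0528). Dcn missed the threshold without WT 1, WT 2, WT 3 or KO A5 (adjusted p up to 0.109). Without the library labelled KO A2 the log2 fold changes were 3.00 for Wnt7b, 3.47 for Csf1, 1.60 for Tinagl1 and 2.69 for Tgm2.

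Among fixed lists in KO EpiLC, for formative epiblast 0 of 23 rose and 4 fell (0 and 5 adjusted over the list alone, median -0.45, camera adjusted p = 0.000405, or 0.394 with an estimated correlation). For glycolysis 0 of 29 rose and 9 fell (0 and 9 adjusted over the list alone, median -0.29, camera adjusted p = 0.00125, or 0.354 with an estimated correlation), and for the respiratory chain 0 of 34 rose and 8 fell (0 and 10 adjusted over the list alone, median -0.24, camera adjusted p = 2.01e-06, or 0.394 with an estimated correlation), with Atp5o and Cyc1 lower. For shared pluripotency 0 of 14 rose and 2 fell (0 and 7 adjusted over the list alone, median -0.31, camera adjusted p = 0.00398, or 0.407 with an estimated correlation), with Utf1 and Cdh1 lower. For p53 targets 8 of 21 rose and 0 fell (10 and 1 adjusted over the list alone, median 0.32, camera adjusted p = 0.000405, or 0.354 with an estimated correlation), led by Perp and Plk2. For endoderm 6 of 17 rose and 0 fell (8 and 0 adjusted over the list alone, median 1.43, camera adjusted p = 3.07e-05, or 0.354 with an estimated correlation), led by Krt8 and Col4a2, and for trophoblast 7 of 16 rose and 0 fell (10 and 0 adjusted over the list alone, median 2.44, camera adjusted p = 0.000462, or 0.421 with an estimated correlation), led by Gata2, Krt8 and Hand1. For fibroblast and mesenchyme 4 of 12 rose and 1 fell (9 and 2 adjusted over the list alone, median 2.00, camera adjusted p = 0.0129, or 0.421 with an estimated correlation), with Acta2 and Tagln higher. For BMP response 6 of 13 rose and 0 fell (7 and 0 adjusted over the list alone, median 1.92 or 1.83 with near-zero genes at their bounds, camera adjusted p = 0.00315, or 0.438 with an estimated correlation), and for LIF and STAT3 response 4 of 14 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.80, camera adjusted p = 0.00145, or 0.438 with an estimated correlation), with Junb and Stat3 higher. For gastrulation mesoderm 3 of 16 rose and 0 fell (4 and 0 adjusted over the list alone, median 2.28 or 1.52 with near-zero genes at their bounds, camera adjusted p = 0.00851, or 0.407 with an estimated correlation), and for dissociation stress 4 of 20 rose and 0 fell (9 and 1 adjusted over the list alone, median 0.66 or 0.60 with near-zero genes at their bounds, camera adjusted p = 0.00294, or 0.407 with an estimated correlation). Without the library labelled KO A2, the calls of the BMP response, LIF and STAT3 response, mesenchyme, cholesterol synthesis, late germ cell and proliferation lists ended, and 11 of 29 lists were called against 15 with it. With genes on chromosomes 1, 8, 11, 16 and Y left out, the calls of the LIF and STAT3 response, mesenchyme, gastrulation mesoderm, late germ cell and proliferation lists ended. Atp5o, Plk2, Gata2 and Hand1 missed the threshold without WT 1, WT 2, WT 3 or the library labelled KO A2 (adjusted p up to 0.0916). Cyc1, Col4a2 and Acta2 missed the threshold without WT 1, WT 2 or WT 3 (adjusted p up to 0.0708). Cdh1 missed the threshold without WT 1, WT 2, WT 3, KO A5 or the library labelled KO A2 (adjusted p up to 0.116). Junb missed the threshold without WT 2 or WT 3 (adjusted p up to 0.0532). Without the library labelled KO A2 the log2 fold changes were 1.29 for Perp, 0.70 for Plk2, 2.62 for Krt8, 1.82 for Col4a2, 2.55 for Hand1, 3.25 for Acta2, 3.1 for Tagln, 2.08 for Junb and 1.16 for Stat3.

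For naive pluripotency 0 of 20 rose and 1 fell (0 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.633, or 0.881 with an estimated correlation). Its median and mean were above 0 (0.14 and 0.33) while the test pointed down, and without the library labelled KO A2 it was lower (camera adjusted p = 4.95e-05). In all, 1424 genes differed between KO and WT EpiLC, 891 higher and 533 lower in KO. This number depended on single libraries: 198, 181 and 182 genes without WT 1, 2 and 3, 2146 without KO A5, 2473 without KO B1 and 596 without the library labelled KO A2. The excess of higher genes was lost without that library (299 higher and 297 lower), without all libraries of line A2 (856 and 932) and without WT 3 (92 and 90). Of the 596, 469 were among the 1424. With the EpiLC libraries fitted alone, edgeR called 0 genes (2425 at an unadjusted p under 0.05), while with all libraries DESeq2 called 1829 and limma-trend 1307. Of 73 named genes past the threshold, 17 passed in each fit without 1 library.

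PGCLC at day 3 were compared between KO and WT to ask what loss of Esrrb changes after germ cell induction. Of naive pluripotency and glycolysis genes 5 of 20 and 6 of 29 were called lower in KO, and of WNT response genes 5 of 11 higher. With an estimated correlation 0 of these lists were called. Nr0b1 (-2.03 ± 0.36, adjusted p = 0.00234), Klf4 (36 ± 8.86 against 134 ± 15.1 CPM, log2 fold change -1.90 ± 0.36, adjusted p = 0.0041), Fgf4 (-1.89 ± 0.39) and Jam2 (-1.48 ± 0.26) fell. Nanog (-0.82 ± 0.34, adjusted p = 0.138) and Tfcp2l1 (-1.37 ± 0.53, adjusted p = 0.117) did not pass. The lactate dehydrogenase gene Ldhb (33.4 ± 8.22 against 254 ± 6.9 CPM, log2 fold change -2.93 ± 0.22, adjusted p = 1.39e-06) and the hexokinase gene Hk1 (-1.80 ± 0.26) fell. Lef1, a transcription factor of WNT signalling, rose (37.2 ± 8.46 against 6.48 ± 0.941 CPM, log2 fold change 2.51 ± 0.30, adjusted p = 7.01e-05), as did Nanos3, an RNA-binding protein of germ cells (2.46 ± 0.40, adjusted p = 0.00156). Pou5f1 rose (0.54 ± 0.15, adjusted p = 0.0311) and Sox2 fell (-0.66 ± 0.16, adjusted p = 0.0172). Pou5f1 missed the threshold without WT 1, WT 2, WT 3 or KO A2 (adjusted p up to 0.16). Sox2 missed the threshold without WT 1, WT 3 or KO B1 (adjusted p up to 0.0784).

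The genes that rose most at day 3 in KO were Eya1, Enpp2, Wnt3, Lgals3bp, Ebf1, Tgm3, Gna14 and Gap43, from 4.01 ± 0.92 for Eya1 to 2.72 ± 0.46 for Gap43. Enpp2, which encodes autotaxin (ENSMUSG00000022425, chromosome 15, 54838901 to 54952892), was at 54.4 ± 9.4 against 3.6 ± 0.477 CPM in KO and WT (log2 fold change 3.90 ± 0.22, adjusted p = 2.88e-08). Those that fell most were Msc (at least 19.2-fold lower), Dner, Mobp, St8sia1, Ism2, Ly6a, Sox21 and Grin1, from -4.65 ± 0.59 for Dner to -3.33 ± 0.38 for Grin1. Eya1 missed the threshold without WT 3 or KO A2 (adjusted p up to 0.0582). Wnt3 missed the threshold without WT 2, WT 3 or KO A2 (adjusted p up to 0.109). Lgals3bp missed the threshold without WT 1 (adjusted p = 0.0564). Ly6a missed the threshold without KO A2 (adjusted p = 0.0514). Without KO A2 the log2 fold changes were 3.33 for Eya1 and 2.36 for Wnt3.

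Among fixed lists at day 3, for naive pluripotency 0 of 20 rose and 5 fell (1 and 8 adjusted over the list alone, median -0.53, camera adjusted p = 0.0022, or 0.691 with an estimated correlation). For glycolysis 0 of 29 rose and 6 fell (0 and 6 adjusted over the list alone, median -0.23, camera adjusted p = 0.000344, or 0.225 with an estimated correlation), with Ldhb, Hk1, Pfkp and Gpi1 lower. For the respiratory chain 0 of 34 rose and 4 fell (0 and 6 adjusted over the list alone, median -0.13, camera adjusted p = 0.00284, or 0.663 with an estimated correlation), with Cox5a lower, and for genes of the mitochondrial genome 3 of 7 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.42, camera adjusted p = 0.00358, or 0.411 with an estimated correlation), with mt-Cytb higher. For WNT response 5 of 11 rose and 0 fell (5 and 0 adjusted over the list alone, median 1.13, camera adjusted p = 0.00159, or 0.225 with an estimated correlation), with Cdx2 (ratio 36, 95% counting interval 5.98 to 1470), Lef1, Sp5 and Ccnd1 higher. For Nodal and activin response 1 of 13 rose and 0 fell (1 and 0 adjusted over the list alone, median 0.45, camera adjusted p = 0.018, or 0.464 with an estimated correlation), the call being of Nodal itself. For FGF and ERK response 5 of 16 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.24, camera adjusted p = 0.00997, or 0.506 with an estimated correlation), led by the immediate early gene Egr1 (2.05 ± 0.27). Egr1 is also a member of the dissociation stress list, whose median was 0.26. For gastrulation mesoderm 4 of 16 rose and 0 fell (6 and 0 adjusted over the list alone, median 1.05, camera adjusted p = 0.0207, or 0.464 with an estimated correlation). For X inactivation 1 of 4 rose and 0 fell (1 and 0 adjusted over the list alone, median 0.57, camera adjusted p = 0.0913, or 0.411 with an estimated correlation). With genes on chromosomes 1, 8, 11, 16 and Y left out, the calls of the Nodal and gastrulation mesoderm lists ended. In all, 1309 genes differed, 643 higher and 666 lower in KO. The number was 692, 621 and 674 without WT 1, 2 and 3, 849 without KO B1 and 816 without KO A2. Of 83 named genes past the threshold, 41 passed in each fit without 1 library. Cdx2, Sp5 and Ccnd1 missed the threshold without WT 1, WT 2, WT 3, KO B1 or KO A2 (adjusted p up to 0.19). Nodal missed the threshold without WT 1, WT 2, WT 3 or KO A2 (adjusted p up to 0.0742).

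PGCLC at day 5 were compared in the same way at the later time. Of WNT and Nodal response genes 6 of 11 and 5 of 13 were called higher in KO, though with an estimated correlation 0 of these lists were called. The Nodal list also lost its call without genes on chromosomes 1, 8, 11, 16 and Y (adjusted p = 0.0539), with a median log2 fold change of 0.67 over 11 members against 0.68 over 13. The early germ cell list was not called (adjusted p = 0.564), with 5 of 19 members higher. Lef1 was at 49.7 ± 20.8 against 4.15 ± 0.424 CPM in KO and WT (3.58 ± 0.31, adjusted p = 2.12e-06). Lefty1, a target and inhibitor of Nodal signalling, rose (3.62 ± 0.83, adjusted p = 0.00691), and so did Nodal (1.83 ± 0.40, adjusted p = 0.00503). The germ cell genes Nanos3 (2.20 ± 0.37) and Prdm1 (1.24 ± 0.26, adjusted p = 0.00406) rose, while Dazl, a later germ cell gene, fell (51.6 ± 16.9 against 90.8 ± 12.6 CPM, log2 fold change -0.82 ± 0.26, adjusted p = 0.0397). Klf4 (-1.44 ± 0.36) and Ldhb (-2.99 ± 0.22, adjusted p = 4.54e-07) fell. Dazl missed the threshold without WT 1, WT 2, WT 3, KO A5 or KO A2 (adjusted p up to 0.162).

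**Figure D3:**
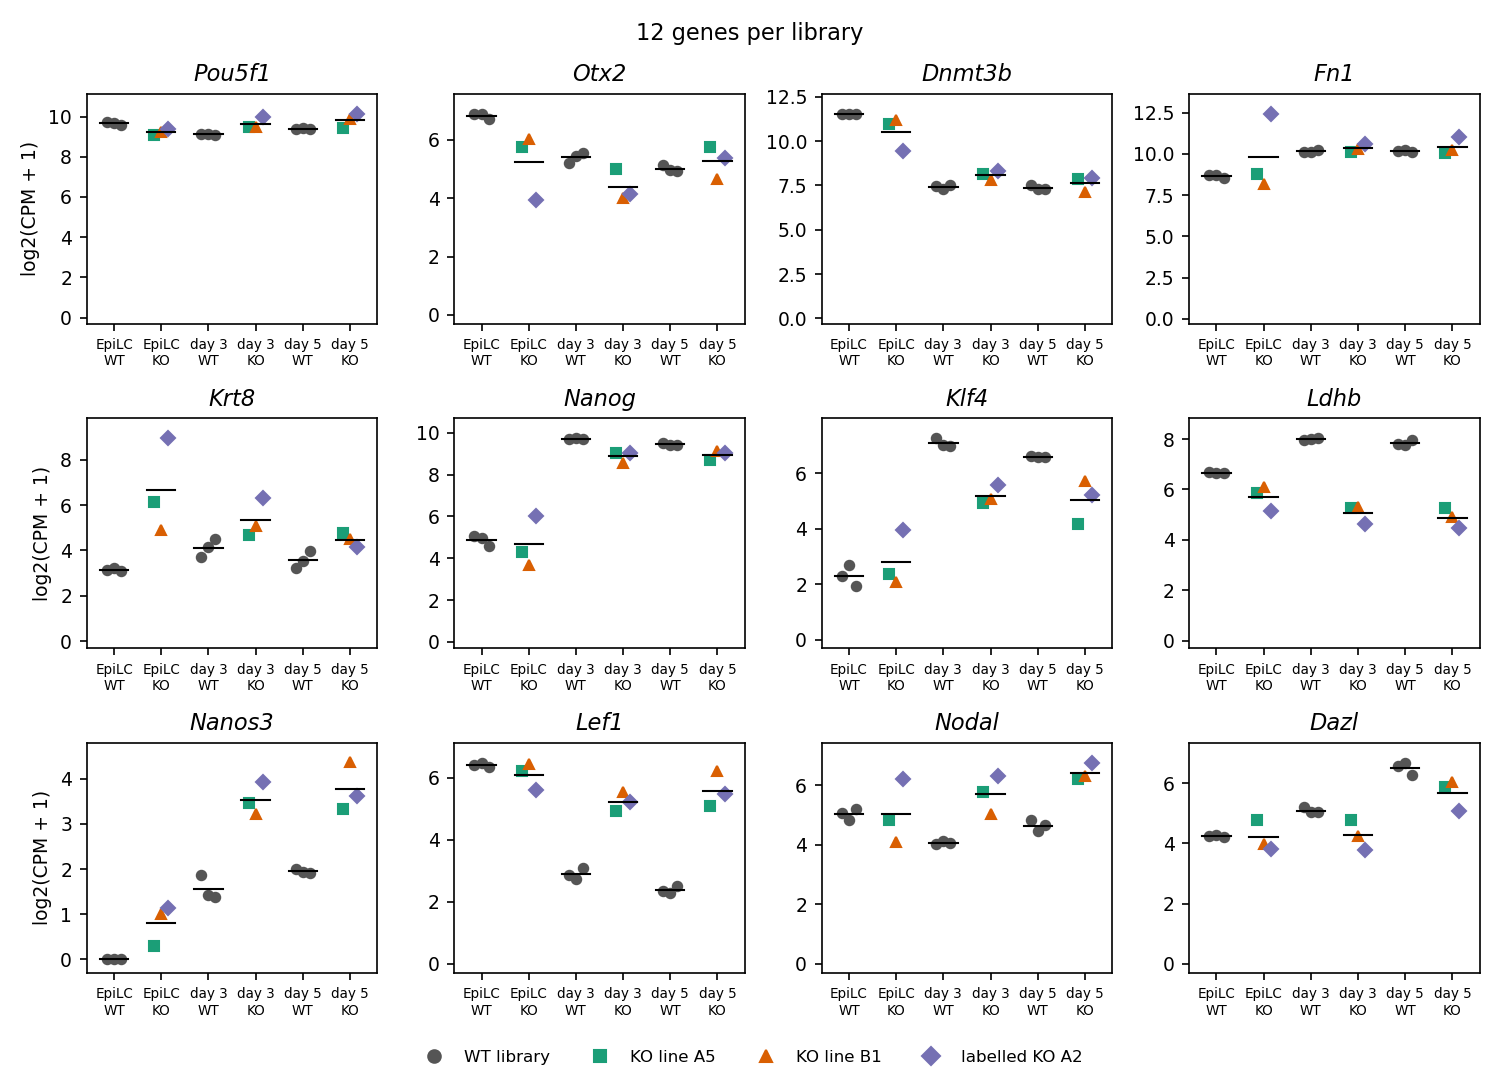
Levels of 12 genes as log2(CPM + 1) for each of the 18 libraries, by stage and genotype, with a line at each group mean. Ldhb is lower and Lef1 higher in the KO than in the WT PGCLC libraries.

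The genes that rose most at day 5 in KO were Eya1 (ratio 84.9, 95% counting interval 28.7 to 415), Bcl11a, Zbp1, Enpp2, Gap43, Gbp1, Ebf1 and Gbp3, from 5.56 ± 0.56 for Bcl11a to 4.46 ± 0.82 for Gbp3. Among those that fell most were Oas1h (ratio 125, 95% counting interval 22 to 4980), Smyd1, St8sia5 (ratio 37.8, 95% counting interval 12.6 to 186), Amn (ratio 28.9, 95% counting interval 9.56 to 143), Ism2, Glod5 and Slc39a2, these ratios being WT over KO. Gbp1, Gbp3 and Oas1h have close relatives in the genome, and how reads shared by them were counted is not given. Without KO A5 the log2 fold change was 3.85 for Gbp1. Without KO A2 the log2 fold change was -4.62 for Smyd1.

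Among fixed lists at day 5, for WNT response 6 of 11 rose and 0 fell (6 and 0 adjusted over the list alone, median 1.49, camera adjusted p = 0.00255, or 0.508 with an estimated correlation), with Lef1, Sp5, Rnf43 and Axin2 higher, the last 2 on chromosome 11, which was shifted downwards in line A2. For Nodal and activin response 5 of 13 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.68, camera adjusted p = 0.00832, or 0.645 with an estimated correlation), with Fst (at least 6.59-fold higher), Lefty1 and Nodal higher. For formative epiblast 4 of 23 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.51, camera adjusted p = 0.00832, or 0.735 with an estimated correlation). For imprinted genes 9 of 31 rose and 3 fell (11 and 3 adjusted over the list alone, median 0.37, camera adjusted p = 0.0276, or 0.593 with an estimated correlation), with Meg3 and Mest higher. For 2-cell-like genes 2 of 4 rose and 0 fell (4 and 0 adjusted over the list alone, median 2.45, camera adjusted p = 0.0452, or 0.735 with an estimated correlation), members of families whose near-identical copies make their counts uncertain. For early germ cell 5 of 19 rose and 1 fell (5 and 2 adjusted over the list alone, median 0.06, camera adjusted p = 0.564, or 0.854 with an estimated correlation), with Rhox5 lower and Nanos3, Ifitm3 and Ifitm1 higher, the last 2 also being interferon-stimulated genes. For DNA methylation machinery 3 of 16 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.05, camera adjusted p = 0.32, or 0.778 with an estimated correlation), with Apobec1 and Dnmt3a higher, and for blood and endothelium 1 of 9 rose and 1 fell (3 and 2 adjusted over the list alone, median 0.47, camera adjusted p = 0.727, or 0.848 with an estimated correlation). For fibroblast and mesenchyme 2 of 12 rose and 0 fell (4 and 0 adjusted over the list alone, median 1.23, camera adjusted p = 0.0452, or 0.735 with an estimated correlation), and for the respiratory chain 0 of 34 rose and 6 fell (0 and 6 adjusted over the list alone, median -0.15, camera adjusted p = 0.00255, or 0.735 with an estimated correlation). With genes on chromosomes 1, 8, 11, 16 and Y left out, the calls of the Nodal, imprinted, 2-cell-like and mesenchyme lists ended. In all, 2244 genes differed, 1264 higher and 980 lower in KO. The number was 1329, 1397 and 1303 without WT 1, 2 and 3 and 1478 without KO A2. Of 94 named genes past the threshold, 60 passed in each fit without 1 library. Sp5 missed the threshold without WT 2 or KO B1 (adjusted p up to 0.0516). Without KO A2 the log2 fold change was 2.33 for Meg3.

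**Figure D4:**
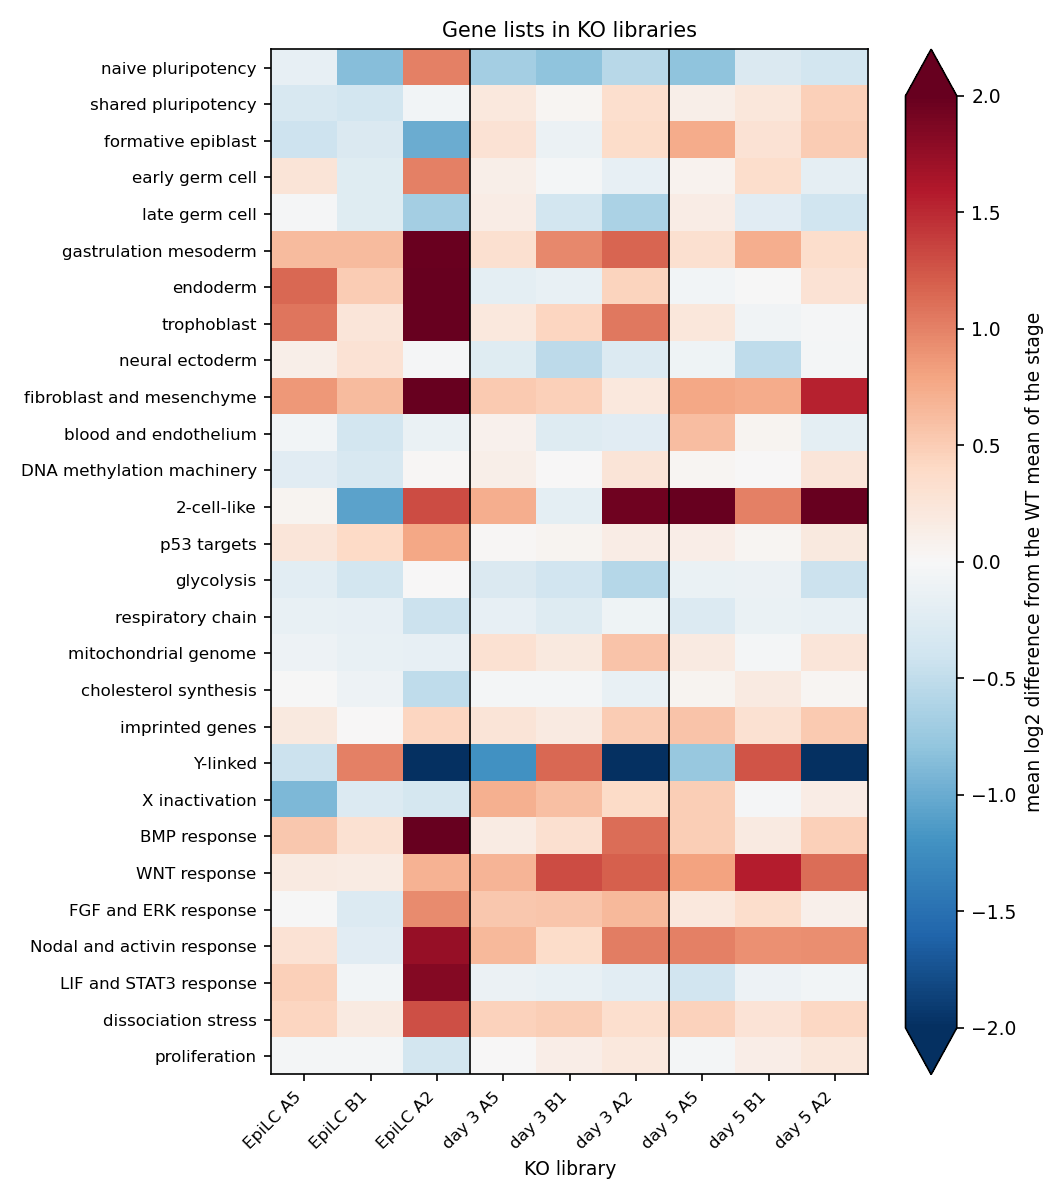
Mean log2 difference from the WT mean of the stage over the members of each fixed gene list with at least 2 tested members (a line per list), for each of the 9 KO libraries (a column per library), with the colour scale ending at -2 and 2. The WNT response list lies between 0.686 and 1.575 in the 6 KO PGCLC libraries.

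Genes changed in the same direction by KO at 2 or more stages numbered 1089, of which 549 were higher and 540 lower, against 187 and 115 expected if calls at the stages were independent. At all 3 stages 58 genes were higher and 40 lower (4.38 and 2.1 expected). Days 3 and 5 shared 954 genes (464 higher, 490 lower, with 63.22 and 50.77 expected) and 0 in opposite directions. EpiLC and day 3 shared 121 in the same direction and 53 in opposite directions, and EpiLC and day 5 shared 210 and 90. The correlation of log2 fold changes across 12856 genes was 0.745 between days 3 and 5, 0.148 between EpiLC and day 3, and 0.136 between EpiLC and day 5, genes not being independent replicates. Ldhb, Hk1, Klf4 and Esrrb fell, and Lef1, Nanos3 and Enpp2 rose, at both days. The stages share no libraries but share the KO lines, so a trait of a line counts at each stage.

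WT EpiLC and WT PGCLC at day 3 were compared for the genes that change on germ cell induction. Most tested naive pluripotency and early germ cell genes rose, and most formative epiblast, neural and cholesterol synthesis genes fell, though with an estimated correlation 0 of these lists were called. Nanog (4.88 ± 0.41), Klf4 (5.03 ± 0.47), Prdm14 (65.6 ± 3.9 against 1.37 ± 0.173 CPM, log2 fold change 5.55 ± 0.40, adjusted p = 3.21e-08) and Tfap2c (5.01 ± 0.44) rose, as did Esrrb (4.48 ± 0.49). Nanos3 was at least 7.6-fold higher. Pou3f1 (-5.86 ± 0.37), Fgf5 (-5.64 ± 0.49), Dnmt3a (-4.00 ± 0.17) and Dnmt3b (172 ± 12.6 against 2937 ± 21.1 CPM, log2 fold change -4.09 ± 0.34, adjusted p = 1.64e-07) fell. Among the genes that rose most were Ly6g6e (at least 168-fold higher), Msx2, Gata2 (ratio 324, 95% counting interval 57.9 to 12800), Rnf182 and Rtp4. Those that fell most were St8sia3 (at least 87.6-fold lower), Slc35d3, Grm6, Btbd17 (ratio 624, 95% counting interval 172 to 5160), Syt4 and Ptn.

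Among fixed lists in this WT step, for naive pluripotency 17 of 20 rose and 1 fell (17 and 1 adjusted over the list alone, median 2.95, camera adjusted p = 5.27e-07, or 0.382 with an estimated correlation), and for early germ cell 15 of 19 rose and 1 fell (15 and 1 adjusted over the list alone, median 2.95 or 2.93 with near-zero genes at their bounds, camera adjusted p = 6.89e-06, or 0.223 with an estimated correlation). For late germ cell 4 of 25 rose and 11 fell (4 and 11 adjusted over the list alone, median -0.83, camera adjusted p = 0.169, or 0.772 with an estimated correlation). For formative epiblast 1 of 23 rose and 19 fell (1 and 19 adjusted over the list alone, median -1.76, camera adjusted p = 3.17e-08, or 0.121 with an estimated correlation), for neural ectoderm 1 of 12 rose and 8 fell (1 and 8 adjusted over the list alone, median -1.93, camera adjusted p = 0.0135, or 0.121 with an estimated correlation), and for cholesterol synthesis 1 of 24 rose and 22 fell (1 and 23 adjusted over the list alone, median -1.15, camera adjusted p = 6.11e-10, or 0.186 with an estimated correlation), with Fdps and Cyp51 lower. For glycolysis 18 of 29 rose and 2 fell (18 and 3 adjusted over the list alone, median 0.90, camera adjusted p = 0.000223, or 0.121 with an estimated correlation), with Hk1 and Pfkp higher, for BMP response 9 of 13 rose and 0 fell (9 and 0 adjusted over the list alone, median 2.52, camera adjusted p = 0.000362, or 0.407 with an estimated correlation), and for LIF and STAT3 response 12 of 14 rose and 1 fell (12 and 1 adjusted over the list alone, median 2.64, camera adjusted p = 1.09e-05, or 0.382 with an estimated correlation). With genes on chromosomes 1, 8, 11, 16 and Y left out, 10 lists were called against 12 with them, and the call of the neural ectoderm list was among those that ended. In all, 7389 genes differed, 3725 higher and 3664 lower at day 3, and 112 of 119 named genes past the threshold passed in each fit without 1 library.

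The same step in KO cells rests in part on the EpiLC library labelled KO A2, whose Esrrb level goes against its label. Nanog (3.90 ± 0.39), Prdm14 (4.63 ± 0.35) and Jam2 (4.93 ± 0.42) rose and Dnmt3a fell (-2.54 ± 0.16, adjusted p = 3.52e-08). The genes that rose most were Ly6g6e (ratio 162, 95% counting interval 28.7 to 6450), Fat2, Osm, Rasgef1a, Trpm1 and Jam2, and those that fell most were Gfra1 (at least 123-fold lower), Spon1, Pcdh18, Btbd17, Wisp1 and Plau. For neural ectoderm 0 of 12 rose and 10 fell (0 and 10 adjusted over the list alone, median -2.80 or -2.53 with near-zero genes at their bounds, camera adjusted p = 2.39e-05, or 0.0123 with an estimated correlation), with Fabp7, Ncam1, Sox1 and Pax6 lower. For naive pluripotency 15 of 20 rose and 1 fell (15 and 1 adjusted over the list alone, median 1.89, camera adjusted p = 7.68e-07, or 0.344 with an estimated correlation), for formative epiblast 2 of 23 rose and 17 fell (2 and 18 adjusted over the list alone, median -1.48, camera adjusted p = 9.74e-07, or 0.159 with an estimated correlation), and for cholesterol synthesis 1 of 24 rose and 22 fell (1 and 23 adjusted over the list alone, median -1.17, camera adjusted p = 4.18e-12, or 0.152 with an estimated correlation). In all, 5394 genes differed, 2646 higher and 2748 lower. With the KO libraries of both stages fitted alone the number was 2161. Fabp7 missed the threshold without EpiLC KO A5, EpiLC KO B1 or day 3 KO A5 (adjusted p up to 0.0602). Without the EpiLC library labelled KO A2 the log2 fold changes were -3.51 for Ncam1 and -2.77 for Sox1.

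The difference between KO and WT in this step was tested as an interaction, which is positive where KO cells rose more or fell less. It rests in part on the EpiLC library labelled KO A2, whose Esrrb level goes against its label. Enpp2 fell from 62.7 ± 3.39 to 3.6 ± 0.477 CPM in WT and went from 25.2 ± 2.5 to 54.4 ± 9.4 CPM in KO (interaction 5.21 ± 0.29, adjusted p = 3.47e-08). Lef1 (2.81 ± 0.38, adjusted p = 0.00078) and Dnmt3a (1.47 ± 0.22, adjusted p = 0.0014) fell less in KO, and Pou5f1 had a positive interaction (0.97 ± 0.21, adjusted p = 0.0147). Klf4 rose less in KO (-2.74 ± 0.66, adjusted p = 0.0236), and the interactions of Ldhb (-2.00 ± 0.30) and Hk1 (-2.33 ± 0.38) were negative too. Esrrb itself did not pass (-1.45 ± 0.67, adjusted p = 0.2). The highest interactions were those of Rassf9, Slc35d3, Insc, Enpp2 and Car14, and the lowest those of Wnt7b, Rin3, Thbd, Ly6a and Serpinb6b. For formative epiblast 5 of 23 had a positive interaction and 0 a negative (9 and 1 adjusted over the list alone, median 0.78, camera adjusted p = 0.00044, or 0.461 with an estimated correlation), and for endoderm 0 of 17 had a positive interaction and 4 a negative (0 and 5 adjusted over the list alone, median -1.74, camera adjusted p = 0.00107, or 0.461 with an estimated correlation). In all, 847 genes differed between the genotypes in this step, 380 with a positive and 467 with a negative interaction. The number was 393, 381 and 405 without EpiLC WT 1, 2 and 3, 442, 361 and 380 without day 3 WT 1, 2 and 3, and 1527 without EpiLC KO B1. Of 52 named genes past the threshold, 23 passed in each fit without 1 library. With the replicate block the number was 1457. Klf4 missed the threshold without EpiLC WT 1, EpiLC WT 3, the EpiLC library labelled KO A2 or day 3 WT 1 (adjusted p up to 0.124). Slc35d3 missed the threshold without day 3 KO A5, day 3 KO B1, any EpiLC WT library or any day 3 WT library (adjusted p up to 0.244). Insc missed the threshold without day 3 KO A5, day 3 KO A2, any EpiLC WT library or any day 3 WT library (adjusted p up to 0.0752). Thbd missed the threshold without the EpiLC library labelled KO A2, day 3 KO A5, day 3 KO B1, day 3 KO A2, any EpiLC WT library or any day 3 WT library (adjusted p up to 0.625). Ly6a missed the threshold without the EpiLC library labelled KO A2, day 3 KO A2, any EpiLC WT library or any day 3 WT library (adjusted p up to 0.41). Serpinb6b missed the threshold without the EpiLC library labelled KO A2 or any EpiLC WT library (adjusted p up to 0.0799). Without the EpiLC library labelled KO A2 the log2 fold changes were -1.76 for Klf4, -5.21 for Wnt7b and -5.36 for Rin3.

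From day 3 to day 5 the fit of all libraries called 99 genes in WT and 71 in KO, and the numbers depended on the fit. In WT the germ cell gene Dazl rose (90.8 ± 12.6 against 33 ± 2.14 CPM at day 5 and day 3, log2 fold change 1.46 ± 0.27, adjusted p = 0.0234) and Fndc3c1 fell (-3.42 ± 0.32, adjusted p = 0.000113). The other genes with the largest changes in WT were Smyd1, Zbtb7c, Gsta3, Dcdc2a, Cd37 and Nckap1l, which rose, and Rtp4, Cachd1, Car4, Aspg and Prom2, which fell. For late germ cell 1 of 25 rose and 0 fell (2 and 1 adjusted over the list alone, median 0.50, camera adjusted p = 0.00603, or 0.871 with an estimated correlation), and for proliferation 0 of 30 rose and 0 fell (0 and 5 adjusted over the list alone, median -0.15, camera adjusted p = 0.000386, or 0.871 with an estimated correlation). In all, 99 genes differed in WT, 37 higher and 62 lower at day 5. The number was 18, 10 and 13 without day 3 WT 1, 2 and 3, and 11, 10 and 18 without day 5 WT 1, 2 and 3. It was 3678 with the WT libraries of both days fitted alone, 3153 by limma-voom with a variance per group and 325 by DESeq2. Dazl, Smyd1, Zbtb7c, Gsta3, Dcdc2a, Cd37, Nckap1l, Rtp4, Car4 and Prom2 missed the threshold without any 1 of the 6 libraries (adjusted p up to 0.212). Cachd1 missed the threshold without day 3 WT 2, day 5 WT 2 or day 5 WT 3 (adjusted p up to 0.0678).

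In KO, Dazl rose from day 3 to day 5 (1.43 ± 0.28, adjusted p = 0.0416) and Fndc3c1 fell (-1.82 ± 0.26, adjusted p = 0.00489). Prmt8, Tuba3b, Myo1f, Ddr2, Cdk5r2 and Bcl11a rose most, and Tmem54, Dab2, Prtg, Sfmbt2 and Fgfr2 were among those that fell most. For late germ cell 3 of 25 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.31, camera adjusted p = 2.44e-05, or 0.275 with an estimated correlation), and for proliferation 0 of 30 rose and 0 fell (0 and 0 adjusted over the list alone, median -0.18, camera adjusted p = 2.44e-05, or 0.413 with an estimated correlation). In all, 71 genes differed in KO, 47 higher and 24 lower, and 216 (133 higher and 83 lower) with the replicate block, as names of KO lines pair the libraries. The number was 9 without day 3 KO B1, 29 without day 5 KO A5 and 33 without day 5 KO B1. It was 873 without all libraries of line A2, and 14 by limma-voom with a variance per group. With the KO libraries of both days fitted alone edgeR called 0 genes (913 at an unadjusted p under 0.05), DESeq2 with all libraries 173 and limma-trend 81. For the interaction of KO with this step edgeR called 0 genes, with 561 at an unadjusted p under 0.05, limma-trend 0, DESeq2 12 and limma-voom with a variance per group 11. Dazl and Tuba3b missed the threshold without day 3 KO B1, day 3 KO A2, day 5 KO A5 or day 5 KO B1 (adjusted p up to 0.159). Prmt8 missed the threshold without day 3 KO A5 or day 3 KO B1 (adjusted p up to 0.0769). Myo1f and Dab2 missed the threshold without day 3 KO A5, day 3 KO B1, day 3 KO A2, day 5 KO A5 or day 5 KO B1 (adjusted p up to 0.158). Ddr2 missed the threshold without day 3 KO A5, day 3 KO B1, day 3 KO A2 or day 5 KO B1 (adjusted p up to 0.159). Cdk5r2 and Sfmbt2 missed the threshold without day 3 KO A5, day 3 KO B1, day 3 KO A2, day 5 KO A5 or day 5 KO A2 (adjusted p up to 0.127). Bcl11a missed the threshold without day 3 KO B1, day 3 KO A2, day 5 KO A5 or day 5 KO A2 (adjusted p up to 0.148). Tmem54 missed the threshold without day 3 KO B1, day 5 KO B1 or day 5 KO A2 (adjusted p up to 0.12). Prtg missed the threshold without day 3 KO B1, day 5 KO A5 or day 5 KO A2 (adjusted p up to 0.0767). Fgfr2 missed the threshold without day 5 KO B1 (adjusted p = 0.0635). Without day 5 KO B1 the log2 fold change was 1.59 for Ddr2.

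Genes of the same chromosome were shifted together in KO lines at every stage. The median log2 ratio to the WT mean of the stage, over 9515 genes with a mean of at least 10 CPM, was -0.481 to -0.422 for chromosome 11 in line A2, and 0.010 to 0.074 in A5. For chromosome 16 it was -0.468 to -0.424 in A2 and -0.475 to -0.418 in B1, and -0.058 to 0.044 in A5. For chromosome 1 it was 0.303 to 0.315 in A2. For chromosome 8 it was smaller and in all 3 lines, -0.184 to -0.129 in A5, -0.147 to -0.087 in B1 and -0.118 to -0.089 in A2. Other chromosomes lay between -0.077 and 0.118 in KO and all chromosomes between -0.04 and 0.051 in single WT libraries. Both of these extremes are of chromosome 8, on which WT libraries differed most (0.020 to 0.051 in WT 2 and -0.040 to -0.013 in WT 3), so the reference itself varies there. The Y-linked genes Ddx3y and Eif2s3y held 0 counts in the 3 libraries of line A2, while in EpiLC Ddx3y held 269, 280 and 249 counts in WT, 165 in KO A5 and 405 in KO B1. In PGCLC Ddx3y was at 16.9 CPM in A5 at both days and at 86.3 and 77.5 CPM in B1, against 39.1 to 52.9 CPM in WT. Eif2s3y went the same way, though not all Y-linked genes were lower in A5. A5 and B1 thus differed from WT in Y-linked genes too. Of the genes named for KO against WT, Tfcp2l1 and Dner lie in the 7 of 13 windows of chromosome 1 that were shifted in A2, Rcsd1, Eya1, Msc and Lefty1 on chromosome 1 outside them, and Cdh1, Col4a2, Junb and Nanos3 on chromosome 8. Hand1, Col1a1, Stat3, Wnt3, Lgals3bp, Ebf1, Bcl11a, Rnf43 and Axin2 lie on chromosome 11, and Atp5o, Gap43 and Jam2 on chromosome 16. For the Y-linked list in EpiLC 0 of 6 rose and 0 fell (0 and 0 adjusted over the list alone, median -0.21, camera adjusted p = 0.417, or 0.805 with an estimated correlation). Genes on chromosomes 1, 8, 11, 16 and Y made 22.6% of those tested and 19.3%, 20.5% and 20.4% of those called between KO and WT in EpiLC, day 3 and day 5. The direction of the calls was skewed on some of them. On chromosome 16, 11.45%, 8.91% and 13.74% of genes were called lower and 2.29%, 1.27% and 4.07% higher at the 3 stages. On chromosome 8, 6.51%, 9.84% and 15.48% were lower and 4.92%, 1.88% and 4.49% higher. On chromosome 1, 2.16%, 4.60% and 5.32% were lower and 7.63%, 4.17% and 10.5% higher, and on chromosome 11, 1.52%, 4.29% and 6.17% were lower and 5.09%, 3.40% and 6.34% higher.

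**Figure D5:**
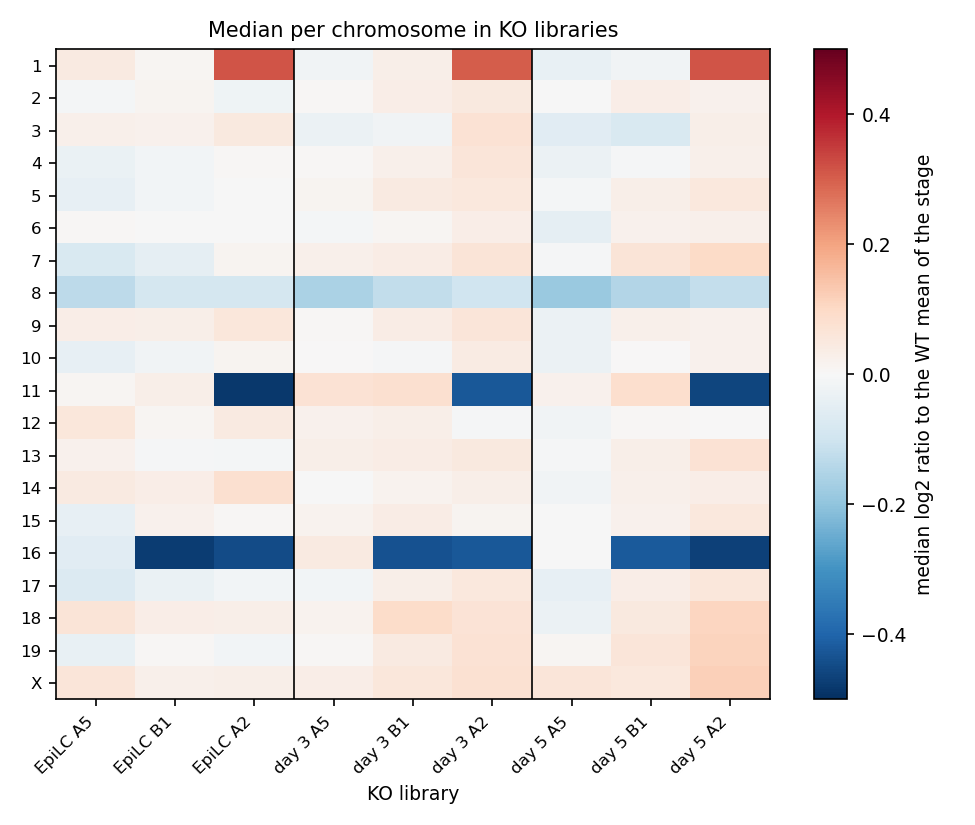
Median log2 ratio of the genes of each chromosome to the WT mean of the stage, for each KO library. Chromosome 11 in line A2 and chromosome 16 in lines A2 and B1 lie below -0.4 at all 3 stages.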

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

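Tests of the EpiLC library labelled KO A2, of the chromosome shifts, of the WNT and Nodal changes (except the share of called members on shifted chromosomes) and of splits that keep KO lines whole were chosen only after the result was seen. The step from EpiLC to day 3 differed between KO and WT for 847 genes by the interaction test. Of 100 drawn splits of the libraries, 1 (the real split) gave as many, and the highest other split gave 345. These splits part the libraries of KO lines, whose names pair them. Of 28 splits that keep each line whole, 1 (the real split) gave as many and the highest other gave 0. Each other split sets a KO line among WT libraries at both stages, which widens the spread within groups where KO has an effect. Counts near 0 were thus likely beforehand. The WT libraries exchanged differ by little more than counting noise, so few of these splits are separate. Chance can thus not be excluded by them for this count. The count itself was 361 to 442 without 1 WT library of either stage. For the later step edgeR called 0 genes (561 at an unadjusted p under 0.05), limma-trend 0, DESeq2 12 and limma-voom 11, with 85 in edgeR without line A2. As any split reaches 0 (100 of 100 did), the splits decide nothing there. The highest of these, 3762, exchanges WT and KO at day 5, which adds the KO effects of both days and points to this structure of the samples.

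The interaction was above 0 for Enpp2 (5.21), Car14 (4.74), Xist (3.35), Lef1 (2.81), Egr1 (2.35), Meg3 (2.13), Dlk1 (2.12), Foxd3 (1.82), Dnmt3a (1.47), Nespas (1.45), Sox4 (1.32), Lin28a (1.27), Ifitm1 (1.22), Apobec1 (1.12) and Foxh1 (1.08). It was smaller but above 0 for Pou5f1 (0.97), Tdrd12 (0.95), Etv5 (0.91), L1td1 (0.84), Ldha (0.77), Gdf3 (0.75), mt-Nd1 (0.65), Mbd3 (0.52), Uhrf1 (0.50) and mt-Co1 (0.45). It was below 0 for Wnt7b (-8.42), Rin3 (-7.48), Col4a2 (-4.94), Tagln (-3.96), Col4a1 (-3.91), Sox21 (-3.57), Klf4 (-2.74), Perp (-2.36), Hk1 (-2.33), Id4 (-2.06), Ldhb (-2.00), Lama1 (-1.83), Sgce (-1.74), Socs3 (-1.72), Mdm2 (-1.46), Btg2 (-1.45), Tek (-1.41), Cdkn1a (-1.36), Cish (-1.27) and P4ha2 (-1.23). Where a group held 3 or fewer counts no fold is given, and the adjusted p was 0.016 for Rassf9, 0.0493 for Slc35d3, 0.0301 for Insc, 0.0485 for Thbd, 0.03 for Ly6a, 0.0204 for Serpinb6b and 0.0497 for Amn. Of these 52 genes, 23 passed in each fit without 1 library and 29 missed the threshold in at least 1 such fit. Without the EpiLC library labelled KO A2 the interaction was -5.21 for Wnt7b, -5.36 for Rin3, -2.17 for Col4a2, -2.43 for Tagln, -1.59 for Col4a1, -1.76 for Klf4, -1.65 for Perp, -1.11 for Socs3 and -0.80 for Mdm2. Klf4, Meg3, Tdrd12, mt-Co1, P4ha2, Thbd, Ly6a and Serpinb6b missed the threshold without it (adjusted p up to 0.625).

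Among lists the interaction with the first step was called upwards for formative epiblast (camera adjusted p = 0.00044), proliferation (0.00155), the mitochondrial genome (0.00176), shared pluripotency (0.0129), DNA methylation machinery (0.031) and WNT response (0.031). It was called downwards for endoderm (0.00107), LIF and STAT3 response (0.00493) and naive pluripotency (0.0376). With the second step the calls were formative epiblast (0.0332), glycolysis (0.0236) and cholesterol synthesis (0.0216) upwards, and the mitochondrial genome (0.0216), trophoblast (0.0332) and FGF and ERK response (0.0332) downwards. With an estimated correlation 0 of these lists were called. Leaving out genes on chromosomes 1, 8, 11, 16 and Y gave 8 and 4 called lists with the first and second step, against 9 and 6. Fry in 1 direction called 6 and 0.

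Counts from the other comparisons rest on 10 splits of 3 against 3 libraries, too few for a share under 0.05. The real and the highest other counts were 1424 and 0 for KO in EpiLC, 1309 and 0 at day 3, 2244 and 0 at day 5, 7389 and 0 for the first step in WT, 99 and 0 for the second step in WT, and 5394 and 470 for the first step in KO. For the second step in KO they were 71 and 418. That split sets both A5 libraries and day 5 B1 against both A2 libraries and day 3 B1, which points to a structure of the samples by KO line, and 3 of 10 splits gave 71 genes or more.

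The EpiLC library labelled KO A2 was weighed first. A library of another line is argued against by its chromosome 11 genes, whose median log2 ratio of -0.481 lies with the PGCLC libraries of line A2 and apart from A5 and B1. Low depth is argued against by its total of 4327028 counts, the highest in EpiLC. The median of the formative list lay -0.53 from that of the shared list (95% interval -1.32 to -0.25). This argues against a mixture of unchanged EpiLC with cells that lack the genes of both lists. Cells that keep part of the shared list could give such a difference too, so a mixture with them stays open. A biological state of line A2 that only this culture took stays open, as does a difference in how this culture was grown, and the single library of this kind tests neither. Its Esrrb counts may be of transcript that the deletion leaves, but this alone does not account for a level above WT. Esrrb was at 39.8 CPM there, against 20.6 to 33.3 in WT EpiLC, 6.71 in KO A5 and 4.54 in KO B1. Nanog and Tfcp2l1 were also higher there than in WT EpiLC, and a link was not tested.

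Chromosome-wide shifts were weighed next. For chromosomes 11 and 16, GC content and transcript length are argued against by matched genes of other chromosomes, whose lowest median was 0.014 in the same libraries. A few strongly changed genes are argued against by the lowest share of genes on the side of the median, 75.5%. A different copy number of chromosomes 11 and 16 is a candidate explanation. Of their 15 Mb windows (9 for 11 in A2, and 6 each for 16 in A2 and B1) 100% were shifted in all 3 libraries of the line. For chromosome 1 in A2 7 of 13 windows were. These 7 were adjacent, from position 15000001 to 120000000. Their means over the 3 libraries were 0.440 to 0.554, against 0.009 to 0.143 in the other windows, so the shift there was of a part of the chromosome. The smaller shift of chromosome 8 was not tested. The medians of chromosomes 11 and 16 in these lines, -0.481 to -0.418, are smaller shifts than loss of a copy from a pair would give if RNA followed copy number. As ratios to WT, they do not say which line is altered. No DNA was measured, so the copy number itself was not tested, and effects of loss of Esrrb and of the state of the lines are shared by design.

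Higher WNT and Nodal response genes in KO PGCLC were weighed last. EpiLC cells carried through the sort are argued against by the called members at day 5, of which 81.8% need a larger share of EpiLC cells than the 48.2% that any silent gene allows. The silent genes mark EpiLC cells only. Other cells of the PGCLC culture that passed the sort were not tested and stay open. A single line is argued against by the means of both lists, which lay above every WT PGCLC library in both PGCLC libraries of each line (WNT at least 0.686 against at most 0.18, Nodal at least 0.368 against at most 0.046). The shifts of chromosomes as the whole source are argued against by 7 of 11 called members of both lists, which lie on other chromosomes. Those on chromosomes 1, 8, 11 and 16 had log2 fold changes at day 5 of at least 1.49 (WNT, 3 of 6 called members) and 3.62 (Nodal, 1 of 5). The 3 WNT members lie on chromosome 11, which was shifted downwards in line A2. Over both lists 0 called members there had a log2 fold change of at most 0.58. This decides nothing, as the lowest of any called member on any chromosome was 0.68. The share of called members on chromosomes 1, 8, 11 and 16, 4 of 11, was larger than the limit written down before. Without genes of these chromosomes and Y the WNT list passed at day 5 (adjusted p = 0.00752), while the call of the Nodal list ended at day 3 (0.018 to 0.0804) and day 5 (0.00832 to 0.0539). Its mean log2 fold change at day 5 went from 1.28 ± 1.73 (SD of 13 members) to 1.11 ± 1.73 (11 members) and its median from 0.68 to 0.67, so the call ended with 2 fewer members and a change about as large. A response of KO cells to signals may underlie the change, and a trait shared by the 3 KO lines but not due to Esrrb stays open.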

How the results depend on the processing

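Leaving out line A2, limma-voom with a variance per group and leaving out genes on chromosomes 1, 8, 11, 16 and Y were chosen only after the result was seen. Of 896 values of named genes, 582 were called in the main fit, and these kept their direction in each alternative that gave them. Direction was not checked for the others. RLE size factors kept 891 of the 896 on their side of the threshold. No filter on low counts ended 57 calls, limma-trend ended 30 and added 5, DESeq2 ended 7 and added 28, and limma-voom ended 90 and added 56. Of 827 values fitted with only the groups compared, 147 calls ended and 55 were added, the most ended by any of these refits. Leaving out line A2 ended 36 and added 51 of 696, and the replicate block ended 9 and added 17 of 550. Leaving out the chromosomes ended 0 and added 4 of 731, but this was no refit. It kept the fold changes and unadjusted p of the main fit, so directions were fixed beforehand and calls could change little. It does not test how the chromosome shifts affect other genes. Leaving out 1 library ended 949 of 6270 and added 47. Where no construction explains a change, the cause was not tested.

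With only the groups compared, the spread comes from fewer libraries and from those groups alone. The counts were 0 for KO in EpiLC, 3678 for the second step in WT, 2161 and 0 for the first and second step in KO, and 456 and 5 for the interactions. Fewer libraries alone would not raise a count from 99 to 3678. Spread was near counting noise in WT and wider in KO, which a spread shared by all groups does not follow. A variance per group in limma-voom moved each of these counts the same way. limma-voom gave 437 for KO in EpiLC, 2099 at day 3, 3153 for the second step in WT, 2733 and 14 for the steps in KO, and 11 for the second interaction. Without line A2 the counts were 2716 at day 3, 3887 at day 5, 873 for the second step in KO, 1912 and 85 for the interactions, and 2199 for agreement between stages. DESeq2 gave 325 and 173 for the second step in WT and KO, and 1277 and 12 for the interactions. With the replicate block the second step gave 387 in WT and 216 in KO, and the first interaction 1457. WT numbers did not pair libraries by the correlation of deviations, though medians of chromosome 8 went with them. No other count was moved over 1.5 times by the block. For the second step in KO, no filter gave 46 and leaving out the chromosomes 47. Agreement at an absolute log2 fold change of at least 1, a stricter rule, was 395.

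Without 1 library, counts ran from 181 to 2473 for KO in EpiLC, 621 to 1463 at day 3 and 1303 to 2189 at day 5. For the steps in WT they ran from 6511 to 6689 and 10 to 18, and in KO from 4468 to 6530 and 9 to 74. For the interactions they ran from 361 to 1527 and 0 to 0. Fewer libraries lower the power of the test, which cannot explain rises such as 1424 to 2473 for KO in EpiLC without KO B1. The cause of such rises was not tested. At 3032965 to 5286330 counts per library, the depth limits genes near 0 counts. In the simulation, whose changed genes lay above a minimum mean CPM, 2-fold changes were recovered for 71.6% at day 3 and 50.7% for the interaction.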

Other observations

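The test of interferon-stimulated genes was chosen only after the result was seen, as Zbp1, Gbp1 and Gbp3 were among the genes that rose most in KO at day 5. Of a list of 40 such genes written down before the test, 33 were tested. At day 5, 20 rose and 1 fell in KO (median log2 fold change 1.74, camera adjusted p = 4.28e-11), and the call ended with an estimated correlation (adjusted p = 0.409). Without line A2 the adjusted p were 1.46e-15 and 0.0728. At day 3, 4 rose and 0 fell (camera adjusted p = 0.00364, or 0.695 with an estimated correlation), and in EpiLC 4 rose and 2 fell (0.0172, or 0.608). From day 3 to day 5 camera called the list lower in WT (median -0.66, adjusted p = 3.38e-12, or 0.737 with an estimated correlation). There 0 members rose and 2 fell, and the fry adjusted p in 1 direction was 0.10. In KO the list was not called (camera adjusted p = 0.972). The interaction was called by camera (1.13e-12, or 0.664 with an estimated correlation) with 0 of 33 members past the threshold and a fry adjusted p of 0.758 in 1 direction. Interferon-stimulated genes may thus be higher in KO PGCLC at day 5, as a hypothesis found and tested on the same libraries, in which the genes of the list move together (estimated correlation 0.315). Zbp1, Gbp1 and Gbp3, which prompted the test, are among the 33 members, and no test without them was run.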
